A study of Mus musculus with 16 samples.

How the data were processed

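Bulk RNA-seq was measured in LLC mouse lung carcinoma cells in 4 groups of 4 libraries: untreated control cells, cells given microwaves, cells given ultraviolet light and serum-starved cells. The labels place the collection of the treated cells at 24 h and describe growth in medium with serum. Starvation appears in the sample titles and not in the treatment text, so its length was taken from the same 24 h. Groups and replicate numbers were read from the sample titles, and all 16 libraries were mapped to a column of each table. The labels describe both removal of ribosomal RNA and selection of poly(A) RNA without saying which was used. Nothing in the labels says that replicates were separate cultures, so the p-values here measure only the spread between these samples, which may be technical.

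Gene-level read counts, deposited by the authors as whole numbers, were the values tested. FPKM values deposited by the authors for the same libraries were used in alternative fits only. The counts covered 28433 genes, of which 28362 also had FPKM values. Reads were aligned to mm10 per the submitters' processing notes. The gene annotation and its version, the strandedness and the handling of reads matching several places are not given there. Over 4044 well-covered genes the ratio of count to FPKM departed from a product of 1 factor per gene and 1 per library by at most 0.850%, so both tables describe the same reads. Genes were kept apart by Ensembl identifier, since 275 symbols were duplicated. Coordinates and lengths came from GENCODE M21 on GRCm38, matched by identifier without its version, which placed 98.2% of the genes. Without strand information, reads of an overlapping gene on the other strand may be counted with a gene. Hspa1a and Hspa1b are nearly identical in sequence, so reads of one may be assigned to the other and their separate values are uncertain.

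Reads assigned to genes numbered 16461408 to 21611493 per library in control, 12215754 to 17266065 in microwave, 14218030 to 17831671 in ultraviolet and 18151776 to 19341945 in starved cells. At these depths, 3 reads in a library correspond to between 0.139 CPM (control replicate 1) and 0.246 CPM (microwave replicate 3). Genes with few reads were removed by filterByExpr (minimum count 10, minimum total 15), which left 14308 genes, 12257 of them protein-coding; the removed genes held at most 0.216% of the reads of any library. The common biological coefficient of variation of the model was 0.216.

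Differences were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, quasi-likelihood F test, one model with 4 group means on all 16 libraries). P-values were adjusted by Benjamini-Hochberg over the 14308 genes, and a gene counted as changed at an adjusted p under 0.05 with no fold threshold. Gene p-values in the text are these unless another tool is named. The 6 comparisons were each treatment with control and each pair of treatments. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of the F statistic, with n = 4 libraries per group throughout. CPM values are group means scaled by TMM factors.

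The 35 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered heat shock, p53 targets, the integrated stress response, endoplasmic reticulum (ER) chaperones, interferon-stimulated genes, NF-kB cytokines, immunogenic cell death, Hmgb1 transport and modification, mitosis, S phase, nucleotide excision repair, apoptosis, pyroptosis and necroptosis, and vesicle shedding. They also covered cholesterol synthesis, fatty acid synthesis, immediate early genes, cytoskeletal targets of SRF and YAP, FOXO targets, autophagy and lysosome, hypoxia and glycolysis, NRF2 targets, MHC class I presentation, extracellular matrix, oxidative phosphorylation, ribosome biogenesis, ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. Markers of macrophages, lymphocytes, fibroblasts, endothelium, erythroid cells and lung epithelium stood for other cell types; fewer than 3 erythroid markers passed the count filter, so 34 lists were tested. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 34 lists of a comparison. This preset assumes that members of a list vary almost independently; the same test with the correlation estimated from the data is given beside each called list whose members are counted, and otherwise for the called lists of a comparison together. Camera ranks a list against all other genes, so its direction can differ from the sign of the list median. Counts of list members are given over all genes tested and adjusted over the list alone.

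The rule for named genes took, against control, the 10 largest rises and the 10 largest falls. Between treatments it took the 5 largest each way. Each needed an adjusted p under 0.05, a mean of at least 10 CPM in the higher group, all 4 libraries of one group above all 4 of the other, and a symbol that is not a clone or predicted-gene name. It added up to 4 members per list with the smallest p, and Hmgb1, Calr, Hspa1a, Hspa1b, Cdkn1a, Atf3, Ddit3 and Hmox1 in every comparison.

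Treatment effects were compared across genes by Pearson correlation and covariance of log2 fold changes, beside simulations of unchanged groups that share the same control libraries. The relation to gene length was the Spearman correlation with genomic length, and with exonic length, tested by exact permutation of the 8 labels of the 2 groups.

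The whole pipeline was tested on counts simulated at the gene means of the control libraries and the spread and depth of the real ones. Of 100 genes given a 2-fold change, 70 (microwave), 69 (ultraviolet) and 75 (starved) were recovered, and of 100 given a 4-fold change 95, 94 and 97, with 7, 7 and 6 calls among unchanged genes. A gene list moved as a whole was called in each comparison, with no other list called. Genes were simulated without correlation, so this says nothing on the preset. A planted trend over gene rank gave a correlation of 0.732 (exact permutation p = 0.0286) and no planted trend gave 0.00129 (exact permutation p = 0.914). A planted covariance between 2 treatment effects of 0.161 was recovered as 0.162. The trend and covariance tests instead used the spread of control libraries, the smallest, and may overstate power.

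Alternatives for the counts of changed genes were RLE factors, library size only, no count filter, DESeq2 1.42.0, limma-voom, limma-trend on log2 of FPKM plus 1 or plus 0.1 (genes with a mean FPKM of at least 1 in a group), the 2 compared groups alone, a 2-fold threshold, the replicate number as a block, and leaving out each library in turn. List tests were repeated with an estimated correlation, with fry, with RLE factors, with the block and without each library. Fry asks whether a list changed at all, not whether it changed more than other genes. Ranges beside list calls are of adjusted p over all alternatives, fry included. After the data were seen, 3 alternatives were added: a fit without microwave replicate 3 and starved replicate 4, limma-voom with quality weights per library, and effects compared without microwave replicate 4 and starved replicate 1. No library was left out of the main analysis.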

Results

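The 4 groups (n = 4 libraries each) were compared over 14308 genes. On average 19077.5 genes were detected per control library, 20161.5 per microwave library, 19130.2 per ultraviolet library and 19440 per starved library (SD 134, 276, 247 and 580). The share of reads on mitochondrial genes was 2.39% (SD 0.131) in control, 2.86% (SD 1.45) in microwave (4.97% in replicate 3, 1.91%, 1.93% and 2.63% in the others), 3.65% (SD 0.176) in ultraviolet and 2.67% (SD 0.423) in starved libraries.

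The first 2 principal components held 32.2% and 21.2% of the variance of the 16 libraries, and the 4 control libraries lay close together. Microwave replicate 3 stood apart from its group: its closest library was ultraviolet replicate 4 (r = 0.963, against 0.940 for the closest microwave library). Starved replicate 4 was closest to ultraviolet replicate 1 (r = 0.979, against 0.959 within its group), and starved replicate 1 to microwave replicate 4. Mitochondrial ribosomal RNA made up 2.13% of the reads of microwave replicate 3 and 0.276% to 0.300% in the other microwave libraries. It was 0.119% (SD 0.00715, n = 4) in control, 0.186% to 0.544% in ultraviolet and 0.0617% to 0.390% in starved libraries. Interferon-stimulated genes, which encode antiviral effectors, varied within the microwave and starved groups. Their mean log2 level relative to control was 1.03 to 1.08 in microwave replicates 1, 2 and 4 and -3.22 in replicate 3. It lay between -4.67 and -4.12 in ultraviolet libraries, and at 0.82, -1.14, -1.94 and -4.34 in starved replicates 1 to 4.

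**Figure D1:**
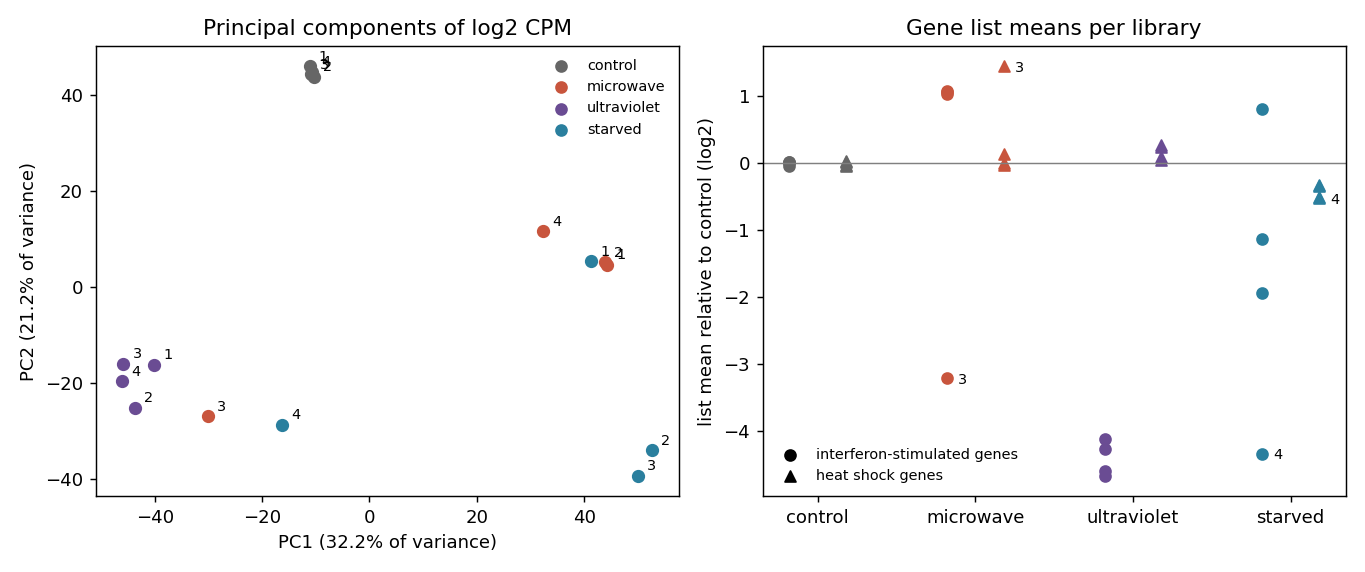
Libraries by principal components of log2 CPM (percent of variance on the axes: 32.2% and 21.2%), and the mean log2 level of the interferon-stimulated and heat shock lists in each library relative to the control mean.

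Cells collected 24 h after microwave treatment had higher levels of immediate early, stress, low-oxygen and lysosomal genes than control cells, and lower levels of cell cycle, respiratory chain and cytoskeletal genes. Immediate early genes rose in 25 of 31, fell in 1 and did not pass in 5 (27 and 1 over the list alone, camera adjusted p = 2.38e-12, adjusted p = 0.130 with an estimated correlation). Fos, an AP-1 subunit (ENSMUSG00000021250.14, chromosome 12, 85473890 to 85477273), rose by 5.79 ± 0.88 (adjusted p = 0.000235), from 0.541 to 30.1 CPM. Its relative Fosb rose by 4.63 ± 0.68 (adjusted p = 0.000176) and Dusp1, a phosphatase of MAP kinases, by 2.16 ± 0.26 (adjusted p = 3.77e-05). Low-oxygen and glycolysis genes rose in 18 of 33 and did not pass in 15 (19 over the list alone, camera adjusted p = 1.03e-08, adjusted p = 0.310 with an estimated correlation). Vegfa, the endothelial growth factor, rose by 2.20 ± 0.12 (adjusted p = 1.88e-08), and Adm, which encodes the vasodilator adrenomedullin, by 2.20 ± 0.22 (adjusted p = 1.25e-05). In the integrated stress response, which follows phosphorylation of eIF2alpha, members rose in 16 of 32, fell in 1 and did not pass in 15 (18 and 1 over the list alone, camera adjusted p = 3.95e-09, adjusted p = 0.316 with an estimated correlation). Its transcription factor Atf3 rose by 2.85 ± 0.25 (adjusted p = 3.44e-06), Ddit3, another of them, by 2.83 ± 0.32 (adjusted p = 2.85e-05) and the cystine transporter Slc7a11 by 2.29 ± 0.25 (adjusted p = 2.34e-05). Autophagy and lysosome genes rose in 18 of 34, fell in 1 and did not pass in 15 (the same over the list alone, camera adjusted p = 5.16e-06, adjusted p = 0.217 with an estimated correlation), among them Bnip3l, a mitophagy receptor, with a rise of 1.14 ± 0.16 (adjusted p = 0.000142). Hmox1, which encodes heme oxygenase, rose by 1.88 ± 0.24 (adjusted p = 7.00e-05).

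NF-kB cytokines rose in 12 of 29 and did not pass in 17 (14 over the list alone, camera adjusted p = 0.000314, adjusted p = 0.221 with an estimated correlation). Cxcl2, a neutrophil chemokine, rose by 2.99 ± 0.49 (adjusted p = 0.000376), or by 2.05 without microwave replicate 3. FOXO targets rose in 12 of 23 and did not pass in 11 (13 over the list alone, camera adjusted p = 0.000145, adjusted p = 0.221 with an estimated correlation), with Klhl24, a ubiquitin ligase adaptor, at 1.91 ± 0.21 (adjusted p = 2.70e-05). P53 targets rose in 11 of 27, fell in 2 and did not pass in 14 (the same over the list alone, camera adjusted p = 0.0205, adjusted p = 0.221 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 2.20 ± 0.29 (adjusted p = 7.48e-05), and Mdm2, the ubiquitin ligase of p53, by 1.01 ± 0.13 (adjusted p = 7.31e-05). Of the p53 list, 1 fell without any 1 control library or microwave replicate 1, 2 or 4. The stress cytokine Gdf15 rose by 2.67 ± 0.33 (adjusted p = 5.27e-05). Among the largest single rises were Nos2, inducible nitric oxide synthase, at 4.67 ± 0.64 (adjusted p = 0.000106), and Mmp10, a matrix metalloproteinase, at 4.65 ± 0.44 (adjusted p = 8.70e-06).

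Genes of S phase fell in 19 of 35 and did not pass in 16 (21 over the list alone, camera adjusted p = 3.83e-11, adjusted p = 0.217 with an estimated correlation). Tk1, which encodes thymidine kinase, fell by 1.38 ± 0.10 (adjusted p = 5.60e-07) and Rrm1, a ribonucleotide reductase subunit, by 0.88 ± 0.12 (adjusted p = 8.57e-05). Mitotic genes fell in 18 of 30 and did not pass in 12 (19 over the list alone, camera adjusted p = 3.95e-09, adjusted p = 0.315 with an estimated correlation), with the mitotic kinase Plk1 at -1.13 ± 0.18 (adjusted p = 0.000341). Nuclear genes of oxidative phosphorylation fell in 23 of 38 and did not pass in 15 (25 over the list alone, camera adjusted p = 6.25e-10, adjusted p = 0.217 with an estimated correlation), such as Atp5g1, a subunit of ATP synthase, at -0.90 ± 0.11 (adjusted p = 5.20e-05). Cytoskeletal targets of SRF and YAP fell in 9 of 21, rose in 1 and did not pass in 11 (10 and 1 over the list alone, camera adjusted p = 0.000261, adjusted p = 0.0378 with an estimated correlation), so this call held with both settings. Cnn2, which encodes a calponin, fell by 1.40 ± 0.21 (adjusted p = 0.000215) and Flna, which encodes filamin A, by 0.84 ± 0.15 (adjusted p = 0.000757). Gpx1, a glutathione peroxidase, was among the largest single falls, at -1.35 ± 0.15 (adjusted p = 2.89e-05).

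Transcripts of Hmgb1, the nuclear protein named in the series title (ENSMUSG00000066551.13, chromosome 5, 149046702 to 149184489), fell in microwave-treated cells by 0.67 ± 0.19 (adjusted p = 0.0146), from 341 to 215 CPM. That call ended without microwave replicate 1 or 2 (highest adjusted p = 0.0507 over all alternatives). Without microwave replicate 3 the log2 fold change of Hmgb1 was -0.94 (adjusted p = 0.000178). Hmgb1 spanned 160 to 325 CPM in microwave and 328 to 358 CPM in control libraries. Calr, which encodes the ER chaperone calreticulin (ENSMUSG00000003814.9, chromosome 8, 84841850 to 84846934), fell by 0.77 ± 0.15 (adjusted p = 0.00164). Both are RNA levels, and the position of the proteins in the cell was not measured. Immunogenic cell death genes rose in 7 of 30, fell in 4 and did not pass in 19 (8 and 5 over the list alone, camera adjusted p = 0.980, no call). Of the cell death list, 4 rose without any 1 control library and 2 fell without microwave replicate 1 or 2. Genes of Hmgb1 transport and modification fell in 8 of 24, rose in 3 and did not pass in 13 (the same over the list alone, camera adjusted p = 0.0868, no call), with the histone deacetylase Hdac1 at -0.70 ± 0.12 (adjusted p = 0.000526). Of the Hmgb1 transport list, 1 rose without control replicate 2, 3 or 4. This list was called without microwave replicate 3 (adjusted p = 0.0247), range 0.00938 to 0.315. Vesicle shedding and scramblase genes fell in 4 of 36, rose in 3 and did not pass in 29 (3 and 3 over the list alone, camera adjusted p = 0.607, no call). Of the vesicle list, 1 fell without control replicate 1 and 2 without control replicate 2.

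Hspa1b, an inducible Hsp70 gene (ENSMUSG00000090877.4, chromosome 17, 34956436 to 34959238), rose by 6.19 ± 1.16 (adjusted p = 0.00104) and its near-identical neighbour Hspa1a (ENSMUSG00000091971.4, chromosome 17, 34969190 to 34972156) by 10.00 ± 1.78 (adjusted p = 0.000724). Hspa1b stood at 77.3, 75.6, 4592 and 117 CPM in microwave replicates 1 to 4, against 15.8 to 17.8 CPM in control. Without replicate 3 the log2 fold changes were 2.43 for Hspa1b and 5.59 for Hspa1a. DESeq2 returned no adjusted p for either gene and limma-voom did not call Hspa1a. Among the alternatives that returned one, the highest adjusted p was 0.0115 for Hspa1b and 0.0995 for Hspa1a. Heat shock genes, these 2 included, fell in 7 of 24, rose in 4 and did not pass in 13 (9 and 4 over the list alone, camera adjusted p = 0.157, no call). Hspa8, a constitutive Hsp70, fell by 0.98 ± 0.12 (adjusted p = 5.20e-05). The median log2 fold change of this list was -0.04, its mean 0.90 and the direction of its test down. Without microwave replicate 3, 11 members fell and the list was called (adjusted p = 0.00547), range 0.00547 to 0.933.

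Of interferon-stimulated genes, edgeR called none of the 43 in the microwave group as a whole, nor over the list alone. At an unadjusted p under 0.05, 5 were higher, while DESeq2 called 1 and limma-voom none. Their median log2 fold change was 0.38 and their mean 0.69, although camera, without a call, put them lower than other genes (adjusted p = 0.828). Without microwave replicate 3, 9 of them rose and the list was called (adjusted p = 0.00866), range 3.90e-05 to 0.983. MHC class I presentation genes rose in 2 of 20 and did not pass in 18 (1 over the list alone, camera adjusted p = 0.828, no call), one riser being Cd274, which encodes the checkpoint ligand PD-L1, at 2.35 ± 0.50 (adjusted p = 0.00256). Of the MHC list, 1 to 8 rose without any 1 of the 8 libraries. The MHC list was called without microwave replicate 3 (adjusted p = 0.00547), range 0.000461 to 0.983. Pyroptosis and necroptosis genes rose in 5 of 13, fell in 1 and did not pass in 7 (the same over the list alone, camera adjusted p = 0.253, no call), among them Casp4, an inflammatory caspase, at 1.47 ± 0.18 (adjusted p = 5.20e-05). The pyroptosis list was called without microwave replicate 3 (adjusted p = 0.0295), range 0.0295 to 0.868. Endothelial markers rose in 2 of 4 and did not pass in 2 (4 over the list alone, camera adjusted p = 0.0534, no call), with Cdh5, the endothelial cadherin, at 2.72 ± 0.51 (adjusted p = 0.00107) and a mean of 2.81 CPM. Of the endothelial list, 1 rose without control replicate 3 or microwave replicate 1. The endothelial list was called without control replicate 1 or 4 or microwave replicate 3 (adjusted p = 0.0455, 0.0392 and 0.0363). Its range was 0.000145 to 0.217.

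In all, 4081 genes changed after microwave treatment (2231 rose and 1850 fell), 1157 of them at least 2-fold (1054 and 103). Simulated recovery was 70% at 2-fold and 95% at 4-fold. Rises made up 54.7% of the calls, against 43.3% on log2 of FPKM plus 1, 43.6% on log2 of FPKM plus 0.1 and 63.7% with library size only. There the median log2 fold change of all genes was 0.11, against 0.06. Camera called 11 of 34 lists, and 20 without microwave replicate 3.

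**Figure D2:**
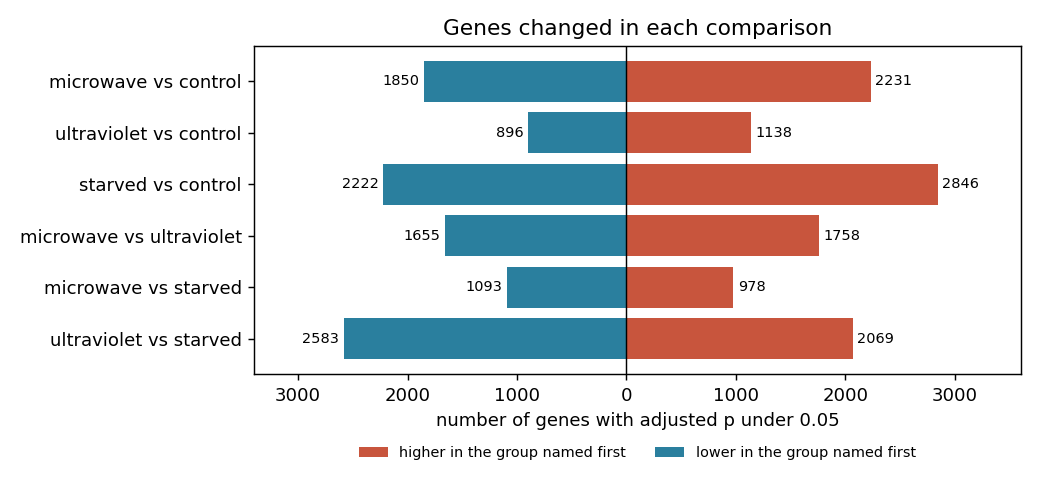
Number of genes that changed in each comparison (edgeR, adjusted p under 0.05), higher and lower in the first group named, for example 2231 and 1850 for microwave against control.

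Ultraviolet-treated cells had very low levels of interferon-stimulated genes, as did microwave replicate 3 and starved replicate 4, and higher levels of cholesterol synthesis, ribosomal protein and immediate early genes than control cells. Interferon-stimulated genes fell in 41 of 43 and did not pass in 2 (42 over the list alone, camera adjusted p = 1.43e-28, adjusted p = 0.221 with an estimated correlation), with a median log2 fold change of -3.94. Ifi44, an interferon-induced gene (ENSMUSG00000028037.14, chromosome 3, 151730922 to 151749960), fell by 8.39 ± 1.40 (adjusted p = 0.00138), from 184 to 0.547 CPM. Oas2, an antiviral oligoadenylate synthetase, fell by 7.62 ± 1.46 (adjusted p = 0.00337). Limma-voom called 23 of the 43 and neither of these genes (highest adjusted p = 0.198 and 0.212). Yet Ifi44 lay at 0.337 to 0.808 CPM in ultraviolet and 160 to 201 in control libraries. It spanned 10.9 to 473 in microwave and 0.727 to 293 in starved libraries. MHC class I presentation genes fell in 6 of 20 and did not pass in 14 (9 over the list alone, camera adjusted p = 0.000139, adjusted p = 0.517 with an estimated correlation), among them Nlrc5, the activator of MHC class I genes, at -1.35 ± 0.33 (adjusted p = 0.0121). Of the MHC list, 1 to 3 fell without any 1 of the 8 libraries. The MHC list did not pass with fry (adjusted p = 0.186), range 4.97e-07 to 0.517.

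Cholesterol synthesis genes rose in 23 of 27 and did not pass in 4 (the same over the list alone, camera adjusted p = 4.85e-17, adjusted p = 0.221 with an estimated correlation). Insig1, a sterol-sensing regulator of SREBP (ENSMUSG00000045294.12, chromosome 5, 28071363 to 28078662), rose by 2.81 ± 0.33 (adjusted p = 0.000103) and Cyp51, a demethylase of sterol synthesis, by 2.60 ± 0.34 (adjusted p = 0.000266). Fatty acid synthesis genes rose in 8 of 17, fell in 1 and did not pass in 8 (11 and 2 over the list alone, camera adjusted p = 0.000392, adjusted p = 0.401 with an estimated correlation), with the phosphatidate phosphatase Lpin1 at 1.97 ± 0.28 (adjusted p = 0.000455). Of the fatty acid list, 4 rose without any 1 control library or ultraviolet replicate 1 or 2. Immediate early genes rose in 15 of 31, fell in 1 and did not pass in 15 (17 and 2 over the list alone, camera adjusted p = 1.33e-06, adjusted p = 0.221 with an estimated correlation). Fos rose by 8.26 ± 0.92 (adjusted p = 6.86e-05), from 0.541 to 167 CPM, and Dusp1 by 3.86 ± 0.27 (adjusted p = 1.17e-06).

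Ribosomal protein genes rose in 32 of 62 and did not pass in 30 (46 over the list alone, camera adjusted p = 8.53e-15, adjusted p = 0.369 with an estimated correlation), such as Rps4x at 0.71 ± 0.11 (adjusted p = 0.000857). Of the ribosomal protein list, 18 rose without control replicate 3 or ultraviolet replicate 2, 20 without control replicate 4 and 21 without control replicate 1 or ultraviolet replicate 4. Ribosome biogenesis genes fell in 4 of 32 and did not pass in 28 (0 over the list alone, camera adjusted p = 0.00136, adjusted p = 0.542 with an estimated correlation). By an unadjusted p under 0.05 the fall held for 9 of them, while DESeq2 called 5 and limma-voom 4. Of the ribosome biogenesis list, 1 or fewer fell without any 1 of the 8 libraries. The ribosome biogenesis list did not pass with fry (adjusted p = 0.232), range 8.32e-05 to 0.542. Mitochondrially encoded genes rose in 3 of 13 and did not pass in 10 (4 over the list alone, camera adjusted p = 0.000389, adjusted p = 0.340 with an estimated correlation), with mt-Co1, a subunit of cytochrome oxidase, at 0.79 ± 0.14 (adjusted p = 0.00209). Nuclear oxidative phosphorylation genes rose in 7 of 38 and did not pass in 31 (the same over the list alone, camera adjusted p = 0.00446, adjusted p = 0.517 with an estimated correlation), among them Ndufa1, of complex I, at 0.99 ± 0.17 (adjusted p = 0.00162). Of the respiratory list, 2 rose without ultraviolet replicate 2, 3 without control replicate 1 or 3 and 4 without control replicate 2 or 4 or ultraviolet replicate 4. The respiratory list was no longer called without ultraviolet replicate 2 (adjusted p = 0.216) and did not pass with fry (adjusted p = 0.0690), range 0.000474 to 0.517. Their median log2 fold change of 0.13 became -0.00 on both FPKM scales.

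Lysosome and autophagy genes rose in 12 of 34 and did not pass in 22 (19 over the list alone, camera adjusted p = 8.35e-09, adjusted p = 0.134 with an estimated correlation), such as Lamp1, a lysosomal membrane protein, at 1.01 ± 0.11 (adjusted p = 7.08e-05). Low-oxygen and glycolysis genes rose in 13 of 33 and did not pass in 20 (16 rose and 1 fell over the list alone, camera adjusted p = 1.06e-07, adjusted p = 0.340 with an estimated correlation), with Ero1a, an ER oxidase, at 1.90 ± 0.28 (adjusted p = 0.000623). NRF2 targets rose in 12 of 27 and did not pass in 15 (15 over the list alone, camera adjusted p = 7.60e-06, adjusted p = 0.0707 with an estimated correlation), among them Tkt, the transketolase of the pentose phosphate pathway, at 0.70 ± 0.11 (adjusted p = 0.00103). Stress response genes rose in 9 of 32 and did not pass in 23 (the same over the list alone, camera adjusted p = 0.000392, adjusted p = 0.542 with an estimated correlation), with Atf3 at 2.76 ± 0.25 (adjusted p = 1.50e-05). Ddit3 rose by 1.23 ± 0.31 (adjusted p = 0.0140), a call lost without ultraviolet replicate 2 or 4 (highest adjusted p = 0.0515). The stress response list did not pass with fry (adjusted p = 0.121), range 2.13e-05 to 0.542. Macrophage markers rose in 3 of 7 and did not pass in 4 (4 over the list alone, camera adjusted p = 0.00351, adjusted p = 0.0803 with an estimated correlation), with Cd74, the invariant chain, at 2.40 ± 0.35 (adjusted p = 0.000568) and 2.10 CPM.

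NF-kB cytokines rose in 7 of 29, fell in 1 and did not pass in 21 (10 and 1 over the list alone, camera adjusted p = 0.000369, adjusted p = 0.239 with an estimated correlation), such as Cxcl2 at 2.39 ± 0.48 (adjusted p = 0.00417). Of the cytokine list, 3 rose without control replicate 4 or ultraviolet replicate 4 and 4 without control replicate 1, 2 or 3. P53 targets rose in 8 of 27 and did not pass in 19 (9 rose and 2 fell over the list alone, camera adjusted p = 0.00540, adjusted p = 0.221 with an estimated correlation). Btg2, an antiproliferative gene, rose by 2.59 ± 0.37 (adjusted p = 0.000468). Cdkn1a rose by 1.08 ± 0.28 (adjusted p = 0.0164), a call lost without control replicate 4 and on both FPKM scales (highest adjusted p = 0.0593). Of the p53 list, 3 rose without control replicate 4, 4 without control replicate 1 or 3 or ultraviolet replicate 4 and 5 without control replicate 2 or ultraviolet replicate 2 or 3. FOXO targets rose in 8 of 23 and did not pass in 15 (10 over the list alone, camera adjusted p = 0.000686, adjusted p = 0.291 with an estimated correlation), with Hbp1, a transcriptional repressor, at 0.71 ± 0.13 (adjusted p = 0.00284). Of the FOXO list, 5 rose without any 1 control library. Targets of SRF and YAP fell in 9 of 21 and did not pass in 12 (10 over the list alone, camera adjusted p = 3.44e-05, adjusted p = 0.0154 with an estimated correlation), a call that held with both settings. Ankrd1, a YAP target, fell by 2.18 ± 0.40 (adjusted p = 0.00270). Of the cytoskeletal list, 5 fell without control replicate 1.

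Hmgb1 (log2 fold change -0.08 ± 0.19, adjusted p = 0.812), Calr (-0.23 ± 0.15, adjusted p = 0.328) and Hspa1b (0.93 ± 0.96, adjusted p = 0.557) did not pass after ultraviolet light. Nucleotide excision repair genes, which act on lesions of ultraviolet light, rose in 1 of 30, fell in 1 and did not pass in 28 (the same over the list alone, camera adjusted p = 0.634, no call). Cetn2, a centrin gene, rose (0.78 ± 0.17, adjusted p = 0.00619) and Lig3, a DNA ligase, fell (-0.59 ± 0.11, adjusted p = 0.00268). Camera called 18 of 34 lists.

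In all, 2034 genes changed after ultraviolet light (1138 rose and 896 fell), 703 of them at least 2-fold (469 and 234). Simulated recovery was 69% at 2-fold and 94% at 4-fold. Without control replicates 1 to 4 the count was 1145, 1239, 1239 and 1202, and without ultraviolet replicate 4 it was 1298. It was 5081 with these 2 groups alone (microwave 4832, starved 4899). It was 3619 without microwave replicate 3 and starved replicate 4, and 5937 with quality weights. Rises made up 55.9% of the calls, 35.6% with library size only and 27.9% and 28.8% on log2 of FPKM plus 1 and plus 0.1. On the last scale the median log2 fold change of all genes was -0.12, against 0.03.

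**Figure D3:**
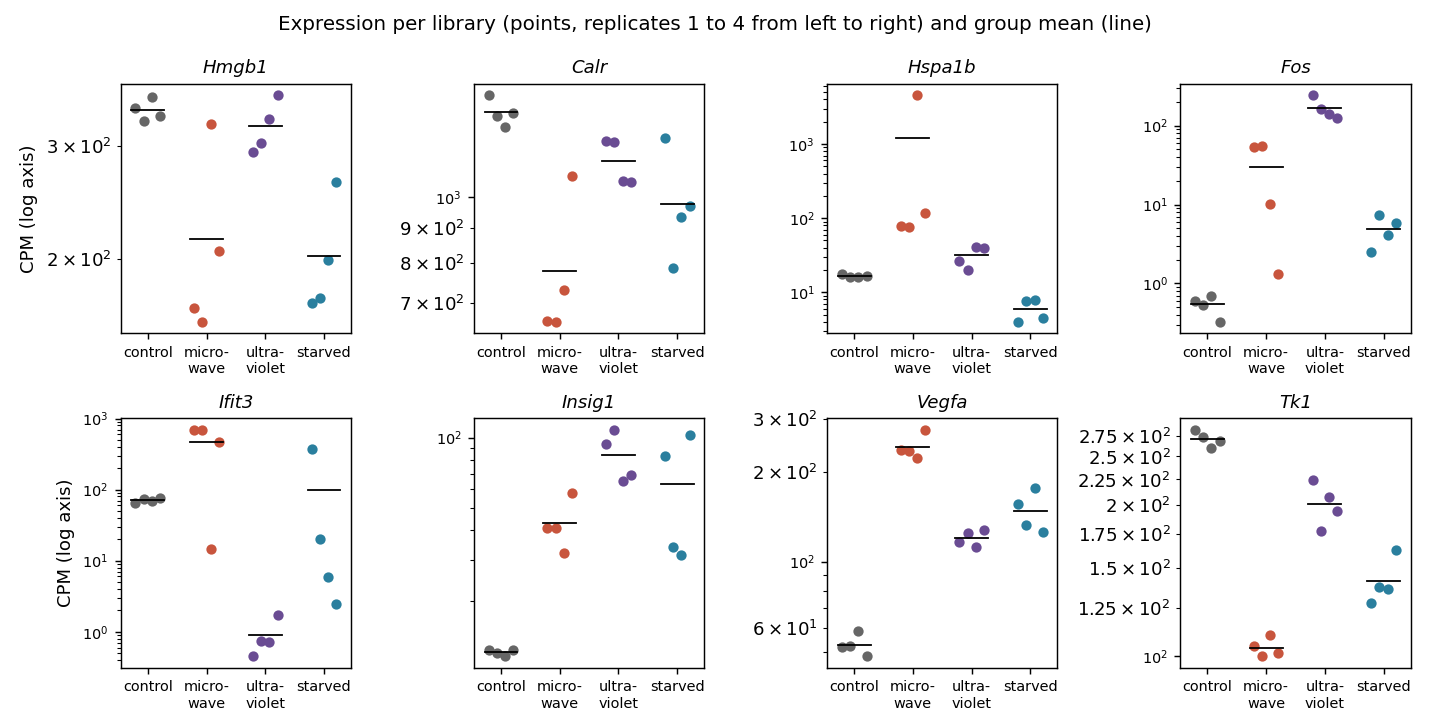
CPM (log axis) of Hmgb1, Calr, Hspa1b, Fos, Ifit3, Insig1, Vegfa and Tk1 in each of the 16 libraries, with a line at each group mean, such as 341 CPM for Hmgb1 in control and 215 CPM in microwave cells.

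Serum-starved cells had higher levels of stress response, lysosomal and FOXO target genes and lower levels of cell cycle and ribosome biogenesis genes than control cells. The integrated stress response rose in 24 of 32 and did not pass in 8 (25 over the list alone, camera adjusted p = 1.76e-09, adjusted p = 0.375 with an estimated correlation). Ddit3 rose by 3.10 ± 0.32 (adjusted p = 8.97e-06) and Pycr1, an enzyme of proline synthesis, by 2.29 ± 0.27 (adjusted p = 2.38e-05). Autophagy and lysosome genes rose in 25 of 34 and did not pass in 9 (27 rose and 1 fell over the list alone, camera adjusted p = 8.09e-11, adjusted p = 0.178 with an estimated correlation). FOXO targets rose in 15 of 23, fell in 1 and did not pass in 7 (16 and 1 over the list alone, camera adjusted p = 1.57e-05, adjusted p = 0.178 with an estimated correlation). Txnip, an inhibitor of glucose uptake (ENSMUSG00000038393.15, chromosome 3, 96557957 to 96561883), rose by 3.98 ± 0.47 (adjusted p = 2.23e-05), from 88.7 to 1403 CPM. Immediate early genes rose in 21 of 31, fell in 2 and did not pass in 8 (25 and 2 over the list alone, camera adjusted p = 1.61e-07, adjusted p = 0.178 with an estimated correlation), with Dusp6, a phosphatase of ERK, at 1.96 ± 0.14 (adjusted p = 1.10e-06). Of the immediate early list, 0 fell without control replicate 1 or 2 and 1 without control replicate 3 or 4 or starved replicate 2, 3 or 4. P53 targets rose in 13 of 27, fell in 2 and did not pass in 12 (13 and 3 over the list alone, camera adjusted p = 0.00187, adjusted p = 0.178 with an estimated correlation), with Gdf15 at 3.97 ± 0.35 (adjusted p = 2.63e-06) and Bbc3, which encodes the cell death protein PUMA, at 2.01 ± 0.22 (adjusted p = 1.49e-05). Of the p53 list, 1 fell without control replicate 1, 2 or 4 or starved replicate 2, 3 or 4. NF-kB cytokines rose in 12 of 29, fell in 1 and did not pass in 16 (the same over the list alone, camera adjusted p = 0.00290, adjusted p = 0.368 with an estimated correlation), with Lcn2, the iron-binding lipocalin, at 4.91 ± 0.74 (adjusted p = 0.000164).

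Mitotic genes fell in 14 of 30 and did not pass in 16 (16 over the list alone, camera adjusted p = 1.35e-08, adjusted p = 0.375 with an estimated correlation). Plk1 fell by 1.31 ± 0.18 (adjusted p = 7.93e-05) and Kif20a, a mitotic kinesin, by 1.03 ± 0.15 (adjusted p = 0.000134). Of the mitotic list, 24 fell without starved replicate 4. S phase genes fell in 12 of 35, rose in 1 and did not pass in 22 (the same over the list alone, camera adjusted p = 0.000154, adjusted p = 0.503 with an estimated correlation), with Tk1 at -0.94 ± 0.10 (adjusted p = 9.62e-06). Ribosome biogenesis genes fell in 9 of 32 and did not pass in 23 (the same over the list alone, camera adjusted p = 0.000215, adjusted p = 0.572 with an estimated correlation), among them Bop1, a nucleolar factor, at -1.15 ± 0.16 (adjusted p = 6.77e-05). Ribosomal protein genes rose in 24 of 62 and did not pass in 38 (the same over the list alone, camera adjusted p = 4.67e-06, adjusted p = 0.615 with an estimated correlation), with Rpl3 at 0.90 ± 0.15 (adjusted p = 0.000363). Of the ribosomal protein list, 12 rose without starved replicate 2 or 3, 13 without control replicate 3 and 15 without control replicate 1 or 4. Oxidative phosphorylation genes fell in 12 of 38 and did not pass in 26 (the same over the list alone, camera adjusted p = 0.00460, adjusted p = 0.572 with an estimated correlation), with Atp5g1 at -0.79 ± 0.11 (adjusted p = 8.50e-05).

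Heat shock genes fell in 8 of 24 and did not pass in 16 (7 over the list alone, camera adjusted p = 0.00262, adjusted p = 0.572 with an estimated correlation), with the Hsp40 cochaperone Dnaja1 at -0.97 ± 0.22 (adjusted p = 0.00279). The heat shock list did not pass with fry (adjusted p = 0.0664), range 0.000542 to 0.572. Hmgb1 fell by 0.76 ± 0.19 (adjusted p = 0.00574), to 202 CPM, and Hmgb1 transport and modification genes fell in 11 of 24, rose in 4 and did not pass in 9 (12 and 5 over the list alone, camera adjusted p = 0.00851, adjusted p = 0.178 with an estimated correlation), with the importin Kpna2 at -0.80 ± 0.12 (adjusted p = 0.000118). Calr fell by 0.44 ± 0.15 (adjusted p = 0.0319), a call lost without control replicate 1, 2 or 4 or starved replicate 2 or 3 (highest adjusted p = 0.107). Cholesterol synthesis genes rose in 14 of 27 and did not pass in 13 (19 over the list alone, camera adjusted p = 0.00326, adjusted p = 0.619 with an estimated correlation), with Insig1 at 2.39 ± 0.33 (adjusted p = 6.77e-05). Of the cholesterol list, 8 rose without starved replicate 1 and 9 without control replicate 4 or starved replicate 4. The cholesterol list was no longer called without starved replicate 1 or 4 (adjusted p = 0.0830 and 0.0651). It did not pass with fry (adjusted p = 0.0966), range 5.85e-06 to 0.619. Interferon-stimulated genes, whose level differed widely between starved libraries, fell in 2 of 43 and did not pass in 41 (1 over the list alone, camera adjusted p = 0.000187, adjusted p = 0.619 with an estimated correlation). Of the interferon list, 1 fell without control replicate 2, 3 or 4 or starved replicate 3 or 4 and 24 without starved replicate 1. The interferon list was no longer called without starved replicate 4 (adjusted p = 0.0651) and did not pass with fry (adjusted p = 0.197), range 9.85e-08 to 0.619. One of the 2 was Samd9l, an antiviral factor, at -2.10 ± 0.53 (adjusted p = 0.00588).

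Extracellular matrix genes rose in 12 of 33, fell in 1 and did not pass in 20 (the same over the list alone, camera adjusted p = 0.00430, adjusted p = 0.303 with an estimated correlation), with Fn1, which encodes fibronectin, at 1.72 ± 0.16 (adjusted p = 4.89e-06). Targets of SRF and YAP fell in 5 of 21, rose in 3 and did not pass in 13 (the same over the list alone, camera adjusted p = 0.0497, adjusted p = 0.178 with an estimated correlation), with the tropomyosin gene Tpm1 at -0.95 ± 0.11 (adjusted p = 1.58e-05). Of the cytoskeletal list, 5 rose without starved replicate 4. The cytoskeletal list was no longer called without control replicate 1 or 4 (adjusted p = 0.0526 and 0.0539). Nor was it without starved replicate 1 or 4 (adjusted p = 0.0535 and 0.178). The call was lost with RLE factors or the replicate block (adjusted p = 0.0520 and 0.0514), range 0.000401 to 0.178. Replication-dependent histone genes fell in 4 of 17 and did not pass in 13 (the same over the list alone, camera adjusted p = 0.0348, adjusted p = 0.619 with an estimated correlation), with H2ac8 at -1.55 ± 0.26 (adjusted p = 0.000354). Of the histone list, 2 fell without starved replicate 2 or 3. The histone list was no longer called without starved replicate 1 (adjusted p = 0.0635) and did not pass with fry (adjusted p = 0.150), range 0.00637 to 0.619. Lung epithelium markers fell in 1 of 4 and did not pass in 3 (the same over the list alone, camera adjusted p = 0.0444, adjusted p = 0.178 with an estimated correlation), the 1 being Krt8, a keratin of simple epithelia, at -1.19 ± 0.15 (adjusted p = 3.86e-05). Of the lung epithelium list, 2 fell without starved replicate 4. The lung epithelium list was no longer called without control replicate 2 or 4 (adjusted p = 0.0696 and 0.0697). Nor was it without starved replicate 1 or 4 (adjusted p = 0.146 and 0.0651), range 0.000147 to 0.178.

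In all, 5068 genes changed in starved cells (2846 rose and 2222 fell), 1493 of them at least 2-fold (1115 and 378). Rises were 56.2% of the calls, 50.7% with library size only, but 47.2% and 46.5% on log2 of FPKM plus 1 and plus 0.1. Simulated recovery was 75% at 2-fold and 97% at 4-fold. Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 3.68 ± 0.47 (adjusted p = 3.86e-05) and Gpx1 by 1.93 ± 0.16 (adjusted p = 1.35e-06). NRF2 targets rose in 14 of 27, fell in 3 and did not pass in 10 (15 and 3 over the list alone, camera adjusted p = 0.00430, adjusted p = 0.178 with an estimated correlation). Camera called 20 of 34 lists with the preset correlation and none with an estimated one.

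**Figure D4:**
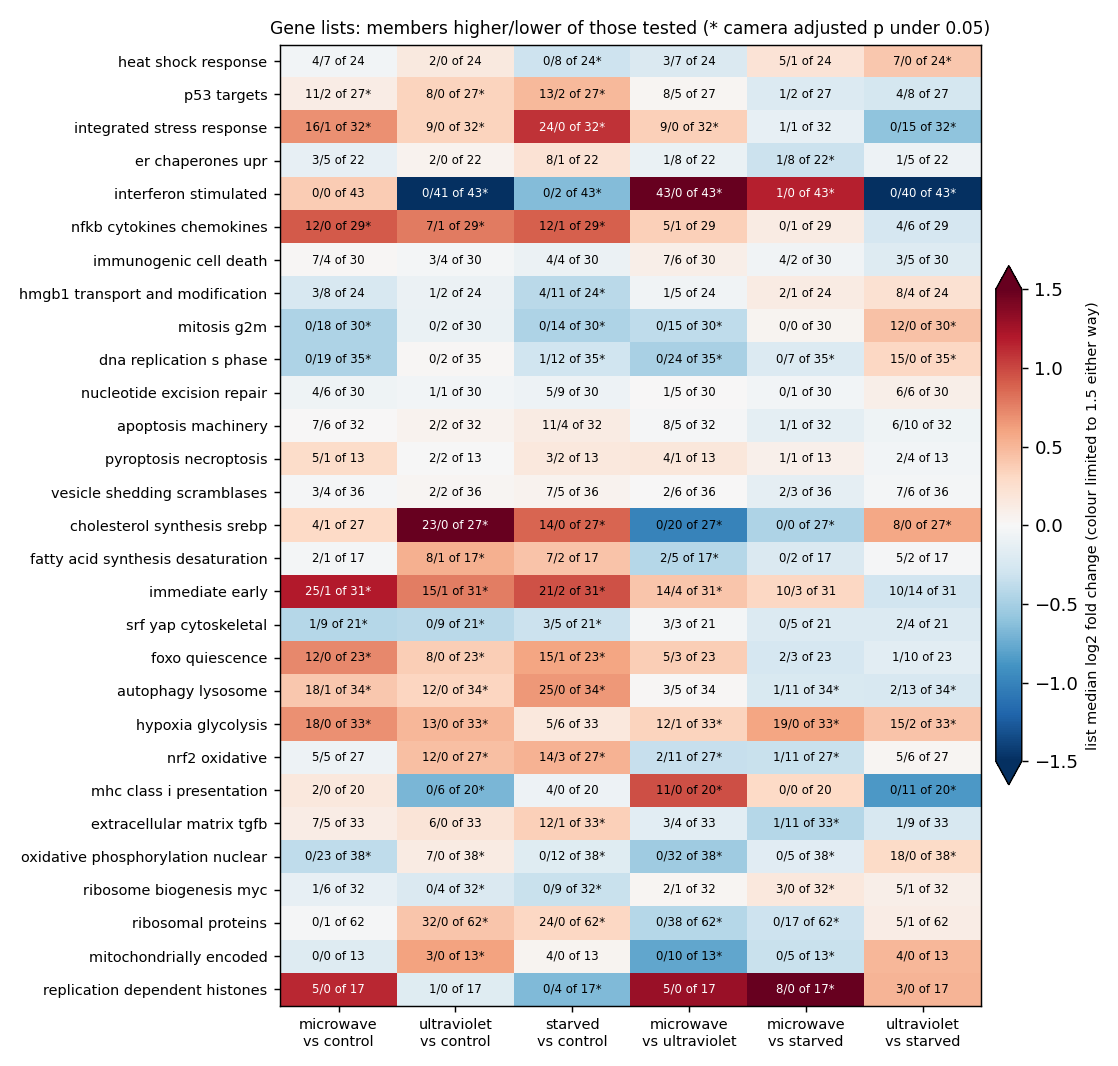
Median log2 fold change (colour, limited to 1.5 in both directions) of each gene list in the 6 comparisons, with a star at a limma camera adjusted p under 0.05. The interferon-stimulated list in ultraviolet cells, at -3.94, exceeds the colour scale.

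Between microwave and ultraviolet cells, all 43 interferon-stimulated genes were higher in microwave cells, also over the list alone, with a median difference of 4.45 log2 units. Their camera adjusted p was 2.62e-21 (0.490 with an estimated correlation). Ifi44 was higher by 9.29 ± 1.43 (adjusted p = 0.000604) and Rsad2, which encodes the antiviral protein viperin, by 8.53 ± 1.41 (adjusted p = 0.000876). Limma-voom called 28 of the 43 and neither of these (highest adjusted p = 0.157 and 0.0575). MHC class I presentation genes were higher in 11 of 20 and did not pass in 9 (14 over the list alone, camera adjusted p = 0.000128, adjusted p = 0.658 with an estimated correlation), with Tap1, a peptide transporter, at 2.10 ± 0.52 (adjusted p = 0.00882). Of the MHC list, 7 were higher without microwave replicate 1 or 2 or ultraviolet replicate 1 or 3 and 18 without microwave replicate 3. The MHC list did not pass with fry (adjusted p = 0.108), range 2.45e-11 to 0.658. Stress response genes were higher in 9 of 32 and did not pass in 23 (10 over the list alone, camera adjusted p = 0.000128, adjusted p = 0.658 with an estimated correlation), with Ddit3 at 1.60 ± 0.31 (adjusted p = 0.00197). The stress response list did not pass with fry (adjusted p = 0.105), range 3.35e-08 to 0.658. Immediate early genes were higher in 14 of 31, lower in 4 and did not pass in 13 (16 and 6 over the list alone, camera adjusted p = 0.00609, adjusted p = 0.658 with an estimated correlation). The transcription factor gene Myc was higher by 1.88 ± 0.24 (adjusted p = 0.000233) and Dusp1 lower by 1.70 ± 0.25 (adjusted p = 0.000415). Vegfa was higher by 1.01 ± 0.12 (adjusted p = 0.000148).

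Oxidative phosphorylation genes were lower in 32 of 38 and did not pass in 6 (36 over the list alone, camera adjusted p = 4.31e-19, adjusted p = 0.238 with an estimated correlation), with Ndufa5, of complex I, at -0.89 ± 0.13 (adjusted p = 0.000386). S phase genes were lower in 24 of 35 and did not pass in 11 (29 over the list alone, camera adjusted p = 9.52e-13, adjusted p = 0.337 with an estimated correlation), with Tyms, the thymidylate synthase, at -1.28 ± 0.25 (adjusted p = 0.00233). Cholesterol synthesis genes were lower in 20 of 27 and did not pass in 7 (22 over the list alone, camera adjusted p = 4.47e-11, adjusted p = 0.490 with an estimated correlation), with Hmgcs1, an early enzyme of the pathway, at -1.67 ± 0.32 (adjusted p = 0.00211). Of the cholesterol list, 13 were lower without microwave replicate 2. Ribosomal protein genes were lower in 38 of 62 and did not pass in 24 (46 over the list alone, camera adjusted p = 1.67e-14, adjusted p = 0.563 with an estimated correlation), with Rps4x at -0.79 ± 0.11 (adjusted p = 0.000348). Of the ribosomal protein list, 21 were lower without microwave replicate 1 or 2, 22 without ultraviolet replicate 2, 23 without microwave replicate 4 and 25 without ultraviolet replicate 4. Camera also called mitotic, fatty acid, NRF2 and mitochondrially encoded genes as lower and low-oxygen genes as higher in microwave cells, 13 of 34 lists in all, none of them with an estimated correlation. The low-oxygen call was lost without microwave replicate 1 or 2, and the low-oxygen and fatty acid lists did not pass with fry. Calls gained were of heat shock genes (without microwave replicate 3 or ultraviolet replicate 1 or 2), pyroptosis and FOXO genes (without microwave replicate 3), and chaperone, histone and fibroblast genes (without microwave replicate 4).

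Hmgb1 was lower in microwave than in ultraviolet cells by 0.59 ± 0.19 (adjusted p = 0.0321), a call lost without any 1 of the 8 libraries except microwave replicate 3 and ultraviolet replicate 1, with library size only and with the 2 groups alone (highest adjusted p = 0.106). Calr was lower by 0.53 ± 0.15 (adjusted p = 0.0180), lost without microwave replicate 1 or 2, with library size only and on both FPKM scales (highest adjusted p = 0.0650). In all, 3413 genes differed (1758 higher and 1655 lower in microwave cells), 900 of them at least 2-fold (723 and 177). The share higher was 51.5%, 77.5% with library size only and 64.2% and 64.4% on log2 of FPKM plus 1 and plus 0.1. With library size only the median difference of all genes was 0.17, against 0.03.

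In microwave cells compared with starved cells, low-oxygen and glycolysis genes were higher in 19 of 33 and did not pass in 14 (21 over the list alone, camera adjusted p = 5.41e-13, adjusted p = 0.365 with an estimated correlation). Egln1, an oxygen-sensing prolyl hydroxylase, was higher by 1.88 ± 0.16 (adjusted p = 1.23e-05) and Angptl4 by 3.69 ± 0.47 (adjusted p = 0.000231). Replication-dependent histone genes were higher in 8 of 17 and did not pass in 9 (10 over the list alone, camera adjusted p = 4.32e-05, adjusted p = 0.581 with an estimated correlation), with H2ac8 at 1.20 ± 0.26 (adjusted p = 0.00717). Of the histone list, 3 were higher without microwave replicate 3 or starved replicate 2 and 5 without starved replicate 3. The histone list did not pass with fry (adjusted p = 0.0519), range 1.58e-07 to 0.581. Interferon-stimulated genes were higher in 1 of 43 and did not pass in 42 (the same over the list alone, camera adjusted p = 1.68e-05, adjusted p = 0.720 with an estimated correlation), the 1 being Samd9l at 2.52 ± 0.54 (adjusted p = 0.00611), lost on log2 of FPKM plus 0.1. Of the interferon list, 14 were higher without microwave replicate 3 and 27 without starved replicate 1. The interferon list was no longer called without starved replicate 4 (adjusted p = 0.0567) and did not pass with fry (adjusted p = 0.322), range 1.22e-18 to 0.720. Ribosome biogenesis genes were higher in 3 of 32 and did not pass in 29 (the same over the list alone, camera adjusted p = 0.00803, adjusted p = 0.725 with an estimated correlation), with Nop56, a nucleolar protein, at 0.60 ± 0.12 (adjusted p = 0.00446). Of the ribosome biogenesis list, 1 were higher without microwave replicate 2 or 3. The ribosome biogenesis list was no longer called without microwave replicate 3 (adjusted p = 0.300) or without starved replicate 4 (adjusted p = 0.545) and did not pass with fry (adjusted p = 0.322), range 0.000802 to 0.725.

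Autophagy and lysosome genes were lower in 11 of 34, higher in 1 and did not pass in 22 (14 and 2 over the list alone, camera adjusted p = 6.34e-05, adjusted p = 0.365 with an estimated correlation), such as Glb1, a lysosomal galactosidase, at -0.91 ± 0.13 (adjusted p = 0.000553). NRF2 targets were lower in 11 of 27, higher in 1 and did not pass in 15 (13 and 1 over the list alone, camera adjusted p = 0.000606, adjusted p = 0.365 with an estimated correlation), with Gstm1, a glutathione transferase, at -1.05 ± 0.13 (adjusted p = 0.000231). Of the NRF2 list, 5 were lower without microwave replicate 1 or 2 and 7 without starved replicate 3. Ribosomal protein genes were lower in 17 of 62 and did not pass in 45 (22 over the list alone, camera adjusted p = 2.93e-11, adjusted p = 0.625 with an estimated correlation), with Rps6 at -0.59 ± 0.12 (adjusted p = 0.00453). Of the ribosomal protein list, 8 were lower without starved replicate 2, 9 without microwave replicate 1, 2 or 4 or starved replicate 3 and 34 without microwave replicate 3. Extracellular matrix genes were lower in 11 of 33, higher in 1 and did not pass in 21 (13 and 5 over the list alone, camera adjusted p = 0.00571, adjusted p = 0.381 with an estimated correlation), with Lama5, a laminin chain, at -1.06 ± 0.16 (adjusted p = 0.000653). ER chaperone genes were lower in 8 of 22, higher in 1 and did not pass in 13 (the same over the list alone, camera adjusted p = 0.00216, adjusted p = 0.581 with an estimated correlation). Of the chaperone list, 4 were lower without microwave replicate 1 or 2.

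Camera also called S phase, oxidative phosphorylation, mitochondrially encoded, cholesterol and fibroblast genes as lower in microwave cells, 14 of 34 lists in all, none of them with an estimated correlation. The cholesterol call was lost without microwave replicate 1, 2 or 3 or starved replicate 1 or 4, the mitochondrial call without microwave replicate 1 or 2 or starved replicate 4, and the fibroblast call without microwave replicate 3 or starved replicate 4. The cholesterol, mitochondrial and S phase lists did not pass with fry. Calls gained without 1 library were of heat shock genes (microwave replicate 1 or 2), cytoskeletal genes (microwave replicate 2), MHC genes (microwave replicate 3 or starved replicate 1), endothelial genes (microwave replicate 3 or starved replicate 2 or 3), fatty acid and immediate early genes (microwave replicate 4 or starved replicate 2 or 3), and mitotic and stress response genes (starved replicate 4). Hmgb1 (log2 difference 0.09 ± 0.19, adjusted p = 0.789) and Calr (-0.33 ± 0.15, adjusted p = 0.157) did not pass between microwave and starved cells, although Calr was called without microwave replicate 4 (highest adjusted p = 0.425 over all alternatives). Hmgb1 was at -0.18 without microwave replicate 3. In all, 2071 genes differed (978 higher and 1093 lower in microwave cells), 571 of them at least 2-fold (446 and 125). The count was 1373 without starved replicate 2, 3173 without microwave replicate 3 and starved replicate 4, and 138 when these 2 groups were fitted alone, where Samd9l, H2ac8, Nop56 and Rps6 were no longer called. The share higher was 47.2%, and 68.4% with library size only.

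By camera with the preset correlation, but not with an estimated one, ultraviolet and starved cells differed in interferon, cell cycle and respiratory chain genes. Immediate early genes were lower in 14 of 31, higher in 10 and did not pass in 7 (the same over the list alone, camera adjusted p = 0.292, no call) in ultraviolet cells, although Fos was higher by 5.08 ± 0.74 (adjusted p = 0.000284) and Dusp1 by 3.38 ± 0.27 (adjusted p = 6.21e-06). Of the immediate early list, 5 were higher without ultraviolet replicate 3 and 6 without ultraviolet replicate 1. The immediate early list was called without starved replicate 4 (adjusted p = 0.0338), range 0.0338 to 0.834. Interferon-stimulated genes were lower in 40 of 43 and did not pass in 3 (42 over the list alone, camera adjusted p = 1.68e-08, adjusted p = 0.686 with an estimated correlation), with Oas2 at -7.47 ± 1.46 (adjusted p = 0.00178), or -6.26 without starved replicate 1. Limma-voom called 2 of them and not Oas2 (highest adjusted p = 0.267). Of the interferon list, 24 were lower without starved replicate 1. The interferon list did not pass with fry (adjusted p = 0.0654), range 4.68e-22 to 0.686. Stress response genes were lower in 15 of 32 and did not pass in 17 (the same over the list alone, camera adjusted p = 7.26e-05, adjusted p = 0.686 with an estimated correlation), with the pseudokinase Trib3 at -1.69 ± 0.31 (adjusted p = 0.00118). The stress response list did not pass with fry (adjusted p = 0.0599), range 1.04e-07 to 0.686. Txnip was lower by 3.62 ± 0.47 (adjusted p = 0.000135).

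Mitotic genes were higher in 12 of 30 and did not pass in 18 (14 over the list alone, camera adjusted p = 5.96e-07, adjusted p = 0.686 with an estimated correlation), with Kif20a at 1.11 ± 0.15 (adjusted p = 0.000223). Of the mitotic list, 22 were higher without starved replicate 4. S phase genes were higher in 15 of 35 and did not pass in 20 (17 over the list alone, camera adjusted p = 0.000161, adjusted p = 0.686 with an estimated correlation), with Mcm5, a helicase subunit, at 0.77 ± 0.15 (adjusted p = 0.00161). Of the S phase list, 9 were higher without ultraviolet replicate 3 or starved replicate 3. Oxidative phosphorylation genes were higher in 18 of 38 and did not pass in 20 (21 over the list alone, camera adjusted p = 3.51e-07, adjusted p = 0.686 with an estimated correlation), with Ndufb8, of complex I, at 0.70 ± 0.12 (adjusted p = 0.000643). Low-oxygen and glycolysis genes were higher in 15 of 33, lower in 2 and did not pass in 16 (17 and 3 over the list alone, camera adjusted p = 0.000211, adjusted p = 0.686 with an estimated correlation), with Ldha, the lactate dehydrogenase, at 1.03 ± 0.14 (adjusted p = 0.000232). Of the low-oxygen list, 5 were lower without starved replicate 4. Heat shock genes were higher in 7 of 24 and did not pass in 17 (the same over the list alone, camera adjusted p = 0.000965, adjusted p = 0.686 with an estimated correlation), with Dnaja1 at 1.21 ± 0.22 (adjusted p = 0.00106). The heat shock list did not pass with fry (adjusted p = 0.0599), range 0.000220 to 0.686. Hmgb1 was higher by 0.67 ± 0.19 (adjusted p = 0.0127). Camera also called MHC class I and autophagy genes as lower and cholesterol genes as higher in ultraviolet cells, 10 of 34 lists in all, none of them with an estimated correlation. The MHC call was lost without starved replicate 1, and did not pass with fry. Other calls gained were of ribosomal protein (without ultraviolet replicate 1 or 3 or starved replicate 3), ribosome biogenesis (replicate 1 of either group), FOXO (ultraviolet replicate 3 or starved replicate 1 or 2), histone (ultraviolet replicate 3 or starved replicate 4), mitochondrial (starved replicate 3 or 4) and Hmgb1 transport genes (starved replicate 3). In all, 4652 genes differed (2069 higher and 2583 lower in ultraviolet cells), 1440 of them at least 2-fold (547 and 893). The share higher was 44.5%, and 33.5% and 34.0% on log2 of FPKM plus 1 and plus 0.1.

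Microwave and starved cells changed many of the same genes: 1353 rose and 1100 fell in both (444 and 287 by chance), and 41 moved in opposite directions (714 by chance). For microwave and ultraviolet cells the counts were 589, 333 and 34 (177, 116 and 287 by chance), and for ultraviolet and starved cells 644, 338 and 49 (226, 139 and 355 by chance). All of these comparisons share the same control libraries. In 20 simulations with unchanged groups the mean correlation of log2 fold changes was 0.465 (0.449 to 0.488) and the mean covariance 0.00887. In the data the covariance was 0.279 for microwave and starved cells, 0.168 for microwave and ultraviolet cells and 0.206 for ultraviolet and starved cells. The correlations over 14308 genes were 0.654 (jackknife SE 0.0394), 0.428 (0.176) and 0.463 (0.136). That of microwave and ultraviolet cells was 0.263 without microwave replicate 3.

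Because lesions of ultraviolet light block transcription more often in long genes, log2 fold changes were compared with gene length over 14265 genes. In ultraviolet cells the median log2 fold change was 0.20 in the shortest decile (median genomic length 1207 bases) and -0.15 in the longest (158592 bases). The Spearman correlation with genomic length was -0.198 in ultraviolet, 0.0120 in microwave and 0.120 in starved cells (exact permutation p = 0.286, 0.857 and 0.429). With exonic length it was -0.214, -0.0115 and 0.0477 (exact permutation p = 0.114, 0.857 and 0.514). None of these trends passed the test, in which the smallest possible p with 70 relabellings is 0.0286. The microwave value with genomic length was -0.0283 without microwave replicate 4.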

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

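All tests of causes in this part were chosen after the results were seen, with bounds written when the values were known. In 18 of 164 groups of 4 values (7 library measures and 34 gene lists) 1 library lay further from the other 3 than the 95% limit of a gap test allows, where chance gives about 1 in 20 groups, or 8.2.

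Microwave replicate 3 stood apart in 8 of these. Its share of mitochondrial ribosomal RNA was 2.13% (nearest microwave library 0.300%), of RNA annotated as miscellaneous 0.283% (0.00383%) and of the 10 highest genes 8.51% (6.34%). Its list means relative to control, in log2 units, were 1.45 for heat shock (nearest 0.13), -3.22 for interferon-stimulated (1.03), -0.35 for pyroptosis (0.62), 0.17 for autophagy (0.47) and -1.26 for MHC class I genes (0.60). Microwave replicate 4 stood apart in stress response genes (1.41, nearest 0.87), ER chaperones (0.28, nearest -0.02) and oxidative phosphorylation (-0.39, nearest -0.35). Among starved libraries, replicate 1 did so in pyroptosis genes (0.62, nearest -0.03) and replicate 4 in ribosome biogenesis (-0.72, nearest -0.27). Starved replicate 2 did so in extracellular matrix genes (0.19, nearest 0.52) and RNA annotated as miscellaneous (0.00175%, nearest 0.000903%). Smaller gaps were seen in FOXO targets of ultraviolet replicate 2 (0.30, nearest 0.41) and in NRF2 targets of ultraviolet replicate 3 (0.53, nearest 0.46) and control replicate 3 (-0.0485, nearest 0.01).

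Interferon-stimulated genes were low in all ultraviolet libraries and also in microwave replicate 3 (-3.22) and starved replicate 4 (-4.34). These 2 were picked for that low level, so their values do not decide whether ultraviolet light was the whole cause. A wrong label was tested with the other genes that differ between the groups, on a scale from 0 (own group) to 1 (ultraviolet). Microwave replicate 3 lay at 0.720 (5354 genes) and starved replicate 4 at 0.625 (6706 genes), below the ultraviolet libraries (lowest 0.931 and 0.926), so a whole ultraviolet library under another label is argued against, and a mixture of RNA was not tested. A state shared by both libraries stays open: outside the interferon list their deviations from their groups correlated at 0.302 (9427 genes). Other pairs holding either (at most 0.0258) are no reference, as deviations of a group cancel out. Microwave replicate 4 and starved replicate 1 reached 0.426, so such likeness was not peculiar to them. Whether that state, not ultraviolet light, lowered the genes in the ultraviolet group cannot be told apart: the ultraviolet effect correlated with the deviation of starved replicate 4 at 0.276 and every ultraviolet library was low.

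Heat shock genes were highest in microwave replicate 3. It held 2788 CPM of the noncoding RNA 7SK, against 20.1 to 29.1 in other microwave libraries and 2.18 to 5.21 in control. That library alone is argued against as the source of the rise of Hspa1b, whose log2 fold change without it was 2.43. More RNA without poly(A) tails stays open as the source: 20 of 22 other heat shock genes were also highest there (37.9% of all genes), but the list was picked for its high mean in this library, so the count does not decide. A response of the whole list in the other microwave libraries is argued against too, as 11 members fell and 4 rose without this library. A stronger or later exposure of this culture may explain the pattern, and this was not tested.

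Chance was tested over the 35 splits of each 8 libraries, and in each comparison only 1, the real one, gave as many genes in edgeR. With control the real and highest other counts were 4081 and 0 for microwave, 2034 and 0 for ultraviolet and 5068 and 1 for starved cells. At an unadjusted p under 0.05 they were 5764 and 2848, 4149 and 813, and 6518 and 3174. Between treatments they were 3413 and 1519 for microwave and ultraviolet (4 other splits with calls), 2071 and 1028 for microwave and starved (9) and 4652 and 1361 for ultraviolet and starved cells (6). The highest other splits grouped microwave replicates 1, 2 and 4 with ultraviolet replicate 1 or starved replicate 1, and ultraviolet replicates 1, 3 and 4 with starved replicate 4, which points to a structure of the samples beyond the groups.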

How the results depend on the processing

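The 3 added alternatives were chosen after the results were seen. In the order microwave, ultraviolet and starved against control, microwave against ultraviolet, microwave against starved and ultraviolet against starved, the counts of changed genes with a 2-fold threshold were 1157, 703, 1493, 900, 571 and 1440. With quality weights in limma-voom they were 9162, 5937, 8692, 7768, 5885 and 7828, the lowest weights being those of microwave replicate 3 (0.143), starved replicates 4 (0.161) and 1 (0.162) and microwave replicate 4 (0.401). Without microwave replicate 3 and starved replicate 4 the counts were 5600, 3619, 6704, 5435, 3173 and 6784. The 2 groups alone gave 4832, 5081, 4899, 2982, 138 and 3340. Leaving out 1 library gave 1145 (control replicate 1) to 1736 (ultraviolet replicate 1) in ultraviolet cells. Between microwave and starved cells it gave 1373 (starved replicate 2) to 2891 (starved replicate 4). Other comparisons and settings, among them the replicate block, stayed within 1.5 times the counts reported. Pairing by replicate number was not clear, as 3 of 24 same-number pairs from different groups had deviations correlated above 0.1. All groups shared 1 model, so the spread of other groups entered each test. Fits of 2 groups left it out: the ultraviolet rise to 5081 points to it, but the fall to 138 may also reflect fewer libraries.

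Camera with an estimated correlation called 1, 1, 0, 0, 0 and 0 of the 34 lists, against 11, 18, 20, 13, 14 and 10 with the preset. Of 86 preset calls, 2 held with the estimated correlation, 85 with RLE factors, 85 with the block and 80 without both libraries (64 lists passed with fry, a test against no change), and 659 of 688 values held when 1 library was left out. In microwave against control cells 20 lists were called without both libraries, and 11 (control replicate 2) to 20 (microwave replicate 3) without 1 library. Ribosome biogenesis in microwave against starved cells changed direction without both libraries (camera adjusted p = 0.539).

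Of the values of named genes in other settings, 358 of 361 held in microwave, 309 of 318 in ultraviolet and 349 of 351 in starved cells against control. Between treatments 186 of 198, 168 of 187 and 187 of 196 held, and only microwave against ultraviolet (2) and microwave against starved cells (2) had changes of direction. Atf3 between microwave and ultraviolet cells, not called at a log2 difference of 0.09, was at -0.21 with quality weights and -0.10 without both libraries, and ranged from -0.10 (without microwave replicate 3) to 0.22 (without microwave replicate 2). Hmgb1 between microwave and starved cells, not called at 0.09, was at -0.15 and -0.0295 in the same settings, with a range of -0.18 (without microwave replicate 3) to 0.24 (without starved replicate 4). The correlation of microwave and starved effects was 0.602 with the controls split 2 and 2, and 0.615 without microwave replicate 4 and starved replicate 1. The length trend in microwave cells ranged from -0.0283 (without microwave replicate 4) to 0.0512 (without microwave replicate 3) with genomic length. With exonic length it was 0.103 over genes of at least 10 CPM, 0.00918 without both libraries and -0.0514 (microwave replicate 4) to 0.00598 (microwave replicate 3) without 1 library, against -0.0115.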

Other observations

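Tests on the likeness of microwave and starved cells were chosen after the results were seen. Effects of microwaves and starvation were alike across genes. Shared control libraries are argued against as the whole cause, since the correlation was 0.602 when each effect had 2 control libraries of its own. Microwave replicate 4 and starved replicate 1, which were alike beyond their groups, are argued against as well, since it was 0.569 without them (jackknife SE 0.0394 with all libraries). A batch of the control libraries apart from all treated ones cannot be told apart from a treatment effect: the highest correlation of a treated with a control library was 0.970, below the lowest among controls (0.992). One hypothesis is that both treatments may limit growth signals or nutrients, which could be tested by phosphorylation of eIF2alpha and S6 kinase in new cultures with controls handled alongside.

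Ifnb1, which encodes interferon beta, varied with the interferon-stimulated genes. Control libraries held 15 to 20 reads of Ifnb1, microwave replicates 1, 2 and 4 held 128, 86 and 65, and microwave replicate 3 none. Starved replicate 1 held 34 Ifnb1 reads and each of the other starved and all ultraviolet libraries at most 1. Because Ifnb1 was picked after its values were seen, a measurement of secreted interferon in new cultures would be needed. Sfpq and Srsf2, which encode splicing factors, fell in starved cells by 1.77 ± 0.30 (adjusted p = 0.000368) and 1.75 ± 0.30 (adjusted p = 0.000406, n = 4 per group).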
